A study of Mus musculus with 8 samples.

How the data were processed

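Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on mouse embryonic fibroblasts (MEF) of the C57BL/6 background, taken at embryonic day 15.5 and grown for 2 to 4 passages. The 8 libraries covered HMGA2, γ-H2AX (H2AX phosphorylated at its C-terminal serine, H2AXS139ph in the labels), the kinase ATM and input DNA, each from Hmga2 wild-type and Hmga2 knockout cells. There was 1 library per antibody and genotype, so no replicate error could be given for any value. Values of 3 wild-type libraries were used, those of HMGA2, γ-H2AX and ATM. The knockout libraries and both inputs were not analysed here, and the comparison of Hmga2 wild-type with knockout cells was therefore not made. The 2 plotting configurations among the deposited data hold no measurement and were not used.

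Per the labels, the authors called peaks in each wild-type library with MACS14, without its shifting model, at a p threshold of 0.01 and with a shift size of 30 bp. The submitters' processing notes also name Trimmomatic, Bowtie2, SAMtools and HOMER, without versions, and the mm10 build. The control library of the peak calls is not stated in the sources used here. Each deposited peak carries a score made by the authors, which is -10 times the log10 of its p, so that a score of 20 stands for the threshold. Scores were used to describe, rank and filter peaks within a list and were not read as amounts of binding. They were set against each other between lists only in rank correlations over shared peaks and in choosing named genes. There, genes with peaks of all 3 antibodies were ranked by their lowest score, and members of each gene list by their highest score in any peak list. The authors also gave region lists of another kind (unit other, start and end only, with no measured value) for promoters with γ-H2AX and promoters with ATM in wild-type cells, and how these promoters were chosen is not stated. A deposited HOMER histogram holds the authors' mean signal (coverage and 5' tags on each strand, per bp and per HMGA2 peak) of the 3 wild-type libraries over 4000 bp around HMGA2 peaks in bins of 1 bp, scaled to 30 M tags per library. It has no column for input.

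Depth was not given as a number. In the histogram, 100% of the tag values were whole multiples, within 0.05, of 1 step per library, against 33.2% for HMGA2, 50.6% for γ-H2AX and 50.1% for ATM with the next best step. If that step is 30 M divided by the tags of the library and rounded to 2 decimals, the libraries held about 30.6 M (HMGA2), 29.4 M (γ-H2AX) and 29.4 M (ATM) tags. This is an inference from the rounding, and no interval for a peak rests on it. Intervals of shares were 95% Wilson intervals and cover counting error only.

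Peaks were overlapped by at least 1 bp with code checked against bedtools 2.31.1, which gave the same 3 counts. The number of overlapping peaks was divided by its mean after 1000 random circular rotations of the second list within each chromosome, and a two-sided p was taken from the position of the observed number among the rotations. The smallest p these could give was 0.002, and 0.00995 for alternatives with 200 rotations. For peaks shared by all 3 lists, both other lists were rotated. Scores of overlapping peaks were compared by Spearman's rho across peaks, which are not independent replicates. The procedure was tested on simulated lists placed at uniform positions, which gave a ratio of 1.01 without planted overlaps and 1.58 with 1500. Such lists share no regional density or background with HMGA2 peaks. They therefore do not test whether sharing of that kind raises the ratio.

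The gene annotation used gives the start and end of each gene on the GRCm38 assembly, to which mm10 coordinates belong, without strand. The planned promoter windows around transcription start sites could not be placed, and the promoter share of peaks was not computed. In its place, windows of 1 kb on either side of both annotated ends of each gene were used, an adaptation made after the data were examined. A gene was counted with an antibody when a peak touched the window at either end, so that peaks of 2 antibodies counted at a gene may lie at opposite ends. The annotation held 49943 genes on the chromosomes of the lists, 21887 of them protein-coding. The share of peaks at gene ends was compared with rotations, and the shares of the lists with each other by Fisher's exact test. The 2 promoter lists were compared by the genes whose windows they touched, and HMGA2 peaks at their regions by Fisher's exact test against windows at all gene ends of like width. Exon, intron and UTR positions were not annotated.

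The 16 gene lists were fixed before the data were examined. They were genes the study is known to have followed, DNA damage response, p53 target genes, TGF-beta signalling, insulin, IGF and mTOR signalling, Wnt signalling, fibroblast and extracellular matrix, immediate early genes, cell cycle, housekeeping, neuronal, blood cell, epithelial, endothelial, Hox genes and olfactory receptor genes. Members with a peak were compared with all other protein-coding genes by two-sided Fisher's exact tests over 3 peak lists and 2 promoter lists, with Benjamini-Hochberg adjustment over all 80 tests at 0.05. Named genes followed a rule fixed at the same time. It took the 10 genes with the highest lowest score among genes with peaks of all 3 antibodies, the 5 highest-scoring genes of each peak and promoter list, up to 4 members of each gene list by score, and Gata6, Mtor, Igf1, Hmga2, H2ax and Atm in any case. Some of the genes it took are not reported here.

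The alternatives fixed in advance were an overlap of at least 50% of the shorter peak, peaks with a score of 50 or more (p of 1e-05 or less), the 10000 highest-scoring peaks of each list, a shift of 50 to 100 kb in place of rotation, fixed intervals of 500 bp, autosomes alone, protein-coding genes alone and scores divided by peak width. The windows of 500 bp and 5 kb were planned for start sites and run at gene ends. Lists matched on CpG content of promoters were planned and not run, as no genome sequence was used here. The comparison of coverage around HMGA2 peaks, densities per chromosome and odds ratios between lists were added after the data were examined. Coverage within 100 bp of the peak centre was divided by that at 1000 to 1800 bp, a range set after coverage was seen to drop at the outer edges of the window. Correlations over the 19 autosomes had p values from 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.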

Results

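HMGA2 is a chromatin protein with AT-hook DNA-binding domains, ATM is a kinase of the DNA damage response that phosphorylates H2AX, and γ-H2AX is the phosphorylated histone. According to the title of the series, the study concerned transcription mediated by HMG proteins and its need for γ-H2AX. The data used here were 3 peak lists from wild-type MEF, with 152834 peaks for HMGA2, 124947 for γ-H2AX and 119570 for ATM. They covered 27.0 Mb, 21.6 Mb and 20.6 Mb of the genome, with median widths of 169 bp, 168 bp and 167 bp. Most peaks lay close to the authors' threshold score of 20. The share with a score under 30 was 88.4% for HMGA2, 89.7% for γ-H2AX and 89.8% for ATM, and 853, 418 and 469 peaks scored 50 or more. Each list came from 1 library, without replicates, so every comparison describes these libraries.

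The highest-scoring peak of all 3 lists lay in the same region of chromosome 14, about 10.5 kb from the pseudogene Gm9637. The region had nearly the same bounds in each list, at 19415574 to 19419721 (HMGA2), 19415681 to 19419718 (γ-H2AX) and 19415616 to 19419715 (ATM). Its scores were 641 for HMGA2, 670 for γ-H2AX and 494 for ATM. A region of chromosome 2 at 98662222 to 98663001 also carried peaks of all 3, with scores of 164 for HMGA2, 204 for γ-H2AX and 214 for ATM. Without input values, high scores of all 3 libraries at these regions cannot be told apart from background that every library shares. They are therefore not read as binding sites. Among the 5 highest-scoring HMGA2 peaks were an X-chromosomal peak at 126770170 to 126773894 (score 346) and a peak within Pbx4, which encodes a homeodomain protein, on chromosome 8 at 69843435 to 69843612 (score 226). The second-highest ATM peak lay within the long non-coding RNA gene Gm40237 on chromosome 4 at 118547187 to 118548739, with a score of 409.

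The next comparison asked whether HMGA2, γ-H2AX and ATM peaks occupied the same places. HMGA2 and γ-H2AX shared 4074 peaks, 2.67% of the HMGA2 list, where rotations gave 2582 on average, a ratio of 1.58 (95% interval 1.53 to 1.63). HMGA2 and ATM shared 3696 peaks, 2.42% of the HMGA2 list, at a ratio of 1.5 (1.45 to 1.55). For γ-H2AX and ATM there were 3348 shared peaks, 2.68% of the γ-H2AX list, at a ratio of 1.68 (1.62 to 1.74). All 3 lists met at 184 HMGA2 peaks against 42.4 after rotation, a ratio of 4.34 (3.74 to 5.02), and 98.5 were expected if the 2 overlaps of HMGA2 were independent. In each case p was 0.002, the smallest the rotations could give. Among peaks with a score of 50 or more, 6, 19 and 17 were shared by the 3 pairs, far above rotation (ratios of 95.2, 247 and 586), and among the 10000 highest-scoring peaks the ratios were 3.33, 4.20 and 6.57, with 13 peaks in all 3 lists against 0.027 after rotation. The regions of chromosomes 14 and 2 described above are among the shared peaks of every pair at both filters. How far these ratios rest on such regions was not tested. With 500 bp intervals the ratio for all 3 lists was 2.36, and with an overlap of at least 50% it was 8.54. Scores of shared peaks were close to unrelated, with Spearman's rho across them of 0.037 for HMGA2 with γ-H2AX, 0.037 for HMGA2 with ATM and 0.033 for γ-H2AX with ATM. Among shared peaks with scores of 50 or more, rho was 0.496 over 19 peaks of HMGA2 with ATM and 0.574 over 17 of γ-H2AX with ATM.

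**Figure D1:**
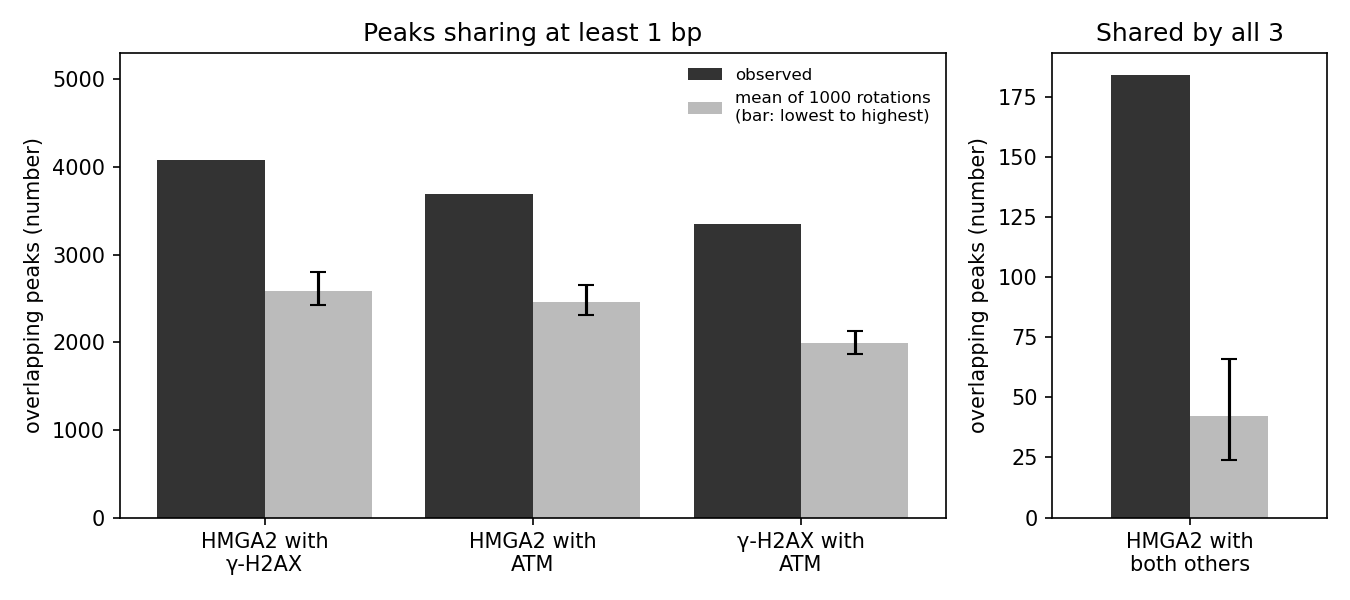
Number of peaks of the first list that share at least 1 bp with the second in wild-type MEF (dark bars) and the mean of 1000 rotations (grey bars, error bars from the lowest to the highest rotation). The observed numbers of 4074, 3696, 3348 and 184 lie above every rotation.

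Mean coverage of all 3 libraries rose at HMGA2 peaks. Within 100 bp of the peak centre, mean coverage per peak and bp was 13.2 for HMGA2, 9.35 for γ-H2AX and 9.37 for ATM, against 4.60, 4.41 and 4.38 in the flanks at 1000 to 1800 bp. The ratios of centre to flank were 2.87, 2.12 and 2.14. The γ-H2AX and ATM profiles had almost the same course, with a correlation across positions of 0.999944, and both had their highest coverage at 133 bp from the centre. The ratio of HMGA2 to γ-H2AX tags was 1.80 at the centre and 1.046 in the flanks. The centres are peaks called in the HMGA2 library itself, so higher HMGA2 values there follow from the choice of sites. No input profile was used here, and neighbouring positions are not independent. As means over all HMGA2 peaks, these values do not show how many peaks carried γ-H2AX or ATM signal. A few sites of very high coverage could shape them, which was not tested. The HMGA2 profile was uneven, at 5.30 at -500 bp and 7.21 at 500 bp, and correlated at 0.985 with γ-H2AX.

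**Figure D2:**
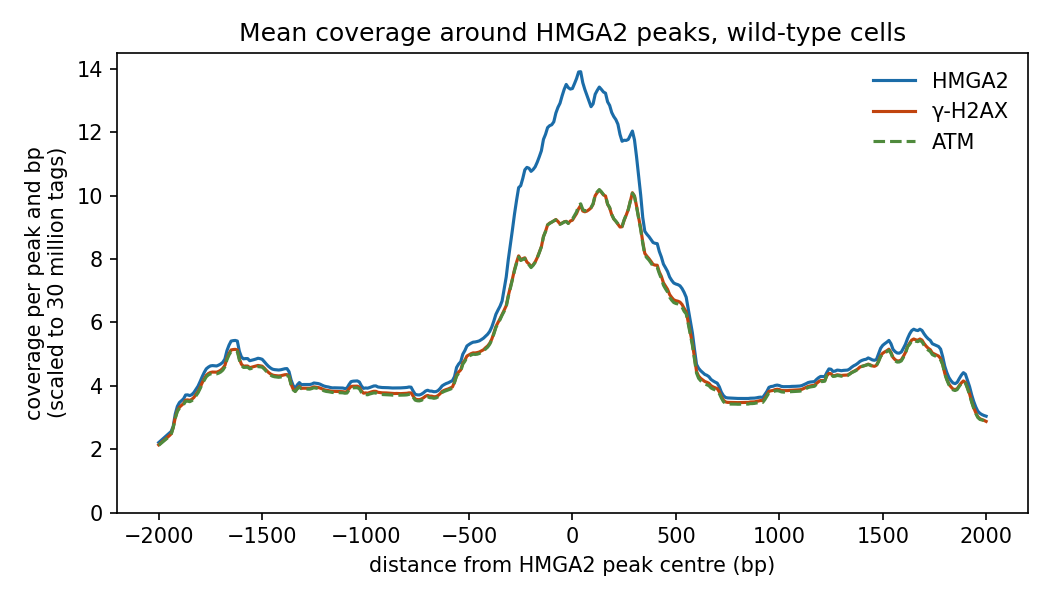
Mean coverage per HMGA2 peak and bp (scaled by the authors to 30 M tags) against the distance from the peak centre in bp for the HMGA2, γ-H2AX (solid) and ATM (dashed) libraries of wild-type MEF. HMGA2 reached 13.9, and γ-H2AX and ATM, whose lines nearly coincide, reached 10.2.

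At gene ends the antibodies differed. Peaks of γ-H2AX lay within 1 kb of a gene end more often than after rotation, 7.80% (7.65 to 7.95) against 6.74%. HMGA2 peaks lay there less often, 5.51% (5.39 to 5.62) against 6.65%, and ATM peaks also, 6.26% (6.12 to 6.40) against 6.71%. In each case p was 0.002, the smallest the rotations could give. Against shifts of 50 to 100 kb, which keep regional density, the deficit of HMGA2 was smaller and like that of ATM. The ratio of HMGA2 was then 0.949 in place of 0.828, that of ATM 0.948 in place of 0.932, and that of γ-H2AX 1.11 in place of 1.16. The odds of a peak lying at a gene end were 1.45 times higher for γ-H2AX than for HMGA2 (Fisher's exact test, p = 5.45e-130), 1.27 times higher for γ-H2AX than for ATM (p = 3.09e-50) and 1.15 times higher for ATM than for HMGA2 (p = 1.02e-16). These odds compare raw shares and leave regional density in. The shifts expected 7.03% for γ-H2AX, 5.80% for HMGA2 and 6.61% for ATM. The odds of ATM against HMGA2 therefore do not show a difference at the gene ends themselves. The exact tests also count peaks as independent, which neighbouring peaks need not be, so their p values may be too small. Around the ends of protein-coding genes, γ-H2AX peaks were densest at 400 to 600 bp outside the gene, at 1.53 times the genome mean, and HMGA2 peaks sparsest at 200 to 400 bp inside, at 0.682 times the mean. HMGA2 was already below the mean farther away, at 0.797 at 4800 to 5000 bp outside and 0.869 at 4800 to 5000 bp inside. It stood higher, at 0.976, at 600 to 800 bp outside. Much of the low HMGA2 level was therefore not confined to the ends. Among the 10000 highest-scoring peaks the ratios to rotation were 1.32 for γ-H2AX and 0.843 for HMGA2 (rotation permutation p = 0.002 for each), whereas the call of ATM was lost (0.933, p = 0.0719). Among the 418 to 853 peaks with a score of 50 or more the ratios were 1.17 for γ-H2AX (0.813 to 1.64), 0.981 for HMGA2 (0.743 to 1.27) and 1.07 for ATM (0.748 to 1.49), none past the threshold, with the values found for every peak inside these intervals.

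**Figure D3:**
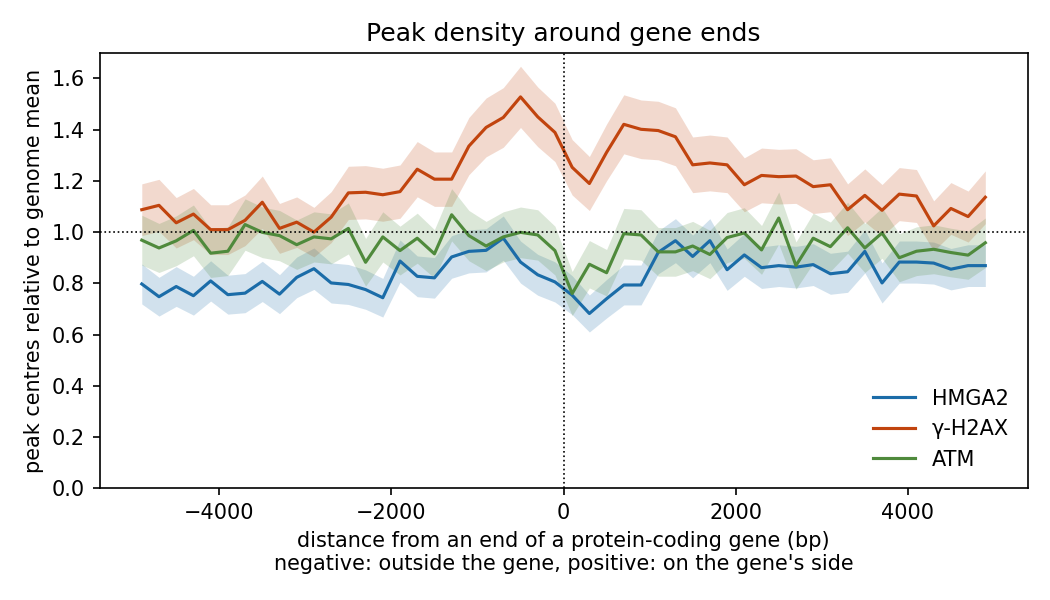
Density of peak centres relative to the genome mean against the distance in bp from an end of a protein-coding gene (negative values outside the gene), in wild-type MEF, with 95% counting intervals as shading. The γ-H2AX line reaches 1.53 outside the gene, whereas HMGA2 falls to 0.682 and ATM to 0.760 just inside.

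Genes with peaks of all 3 antibodies at an end included Id2, an inhibitor of basic helix-loop-helix transcription factors (chromosome 12, 25093799 to 25096092), with scores of 27.5 for HMGA2, 29.8 for γ-H2AX and 26.9 for ATM. Sema3c, a secreted semaphorin (chromosome 5, 17574816 to 17730268), had scores of 26.5, 36.5 and 43.3 in the same order. Both genes were in both promoter lists. In Id2 these γ-H2AX and ATM peaks overlapped outside one end and the HMGA2 peak lay at the other, where a weaker γ-H2AX peak (20.5) was also found, whereas in Sema3c all 3 lay around the same end. Others among the 10 highest were Ect2, a guanine nucleotide exchange factor of cytokinesis, with a γ-H2AX score of 43.1, and Tada2a, an adaptor of histone acetyltransferases, with an HMGA2 score of 41.2. Tbx18, a T-box transcription factor (ATM score 30.9), Pfdn2, a prefoldin subunit (ATM score 30.7), Zfp809, a zinc-finger repressor of retroviral DNA (γ-H2AX score 39.8), and Denn2b (γ-H2AX score 33.5) followed, with the predicted genes Gm51573 and Gm38664. In Ect2 and Tbx18 the γ-H2AX peak lay at the opposite end of the gene from the HMGA2 and ATM peaks. The ATM peak did so in Tada2a and Pfdn2, and the HMGA2 peak in Zfp809. In Denn2b the higher HMGA2 peak (28.0) lay opposite the others, and a weaker one (20.5) at their end.

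Of the 21887 protein-coding genes, 3915 (17.9%) had an HMGA2 peak at an end, 5105 (23.3%) a γ-H2AX peak and 3531 (16.1%) an ATM peak. HMGA2 and γ-H2AX met at 1171 genes against 913 expected from independent sets (odds ratio 1.52, Fisher's exact test, p = 7.34e-26), HMGA2 and ATM at 786 against 632 (1.39, p = 4.87e-13), and γ-H2AX and ATM at 985 against 824 (1.34, p = 5.37e-12). All 3 met at 246 genes, 1.67 times the expected number. Differences between genes in base composition or mappability were not modelled.

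No gene was among the 5 highest-scoring of more than 1 antibody. For HMGA2 these were Tmem263 (score 107), Nfkb1, which encodes an NF-κB subunit (69.3), Rnf7, a RING component of ubiquitin ligases (60.9), and Fabp1, the fatty acid-binding protein of liver (60.02). Zfp985 (83.3) lies in a family of near-identical zinc-finger genes and its assignment is uncertain. For γ-H2AX they were Noct, which encodes nocturnin (69.2), Alg9, a mannosyltransferase of N-glycosylation (61.1), Sesn2, a stress-induced inhibitor of mTOR signalling (60.8), Foxc2, a forkhead transcription factor (60.7), and Fibin (59.9). For ATM they included Mreg (65.9), Lbr, the lamin B receptor (59.0), and Mrpl17, a protein of the mitochondrial ribosome (57.9). Serpinb9d, also at 59.0, belongs to a tandem family and is uncertain.

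The γ-H2AX promoter list held 2220 regions, each identical to a γ-H2AX peak, and the ATM promoter list held 866, of which 788 were identical to an ATM peak and 78 matched none. Noct, Alg9 and Sesn2 led the first list, followed by Ints1, a subunit of the Integrator complex (score 59.8), and Lurap1l (56.9). Among the highest of the other were Lbr, Spef1 and the chemokine receptor gene Xcr1 (51.1). The lists had 155 genes in common against 45.6 expected (ratio 3.40, Fisher's exact test, p = 4.33e-41). Among protein-coding genes alone they had 127 in common against 68.1, a ratio of 1.87 (exact p = 3.87e-12). Most genes touched were protein-coding, 1976 of 2423 (γ-H2AX) and 754 of 940 (ATM), unlike the 49943 genes of the background. The ratio over all genes was raised by this. Of the 866 ATM regions, 49 shared at least 1 bp with a γ-H2AX region, a count for which no expected number was computed. Of all ATM peaks, 2.79% touched a peak of the much longer full γ-H2AX list. The count of 49 is therefore not read as low.

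HMGA2 peaks were found at 66 of the 2220 γ-H2AX promoter regions, 2.97% (2.34 to 3.76), against 1.503% of windows at all gene ends (odds ratio 2.01, Fisher's exact test, p = 7.13e-07). They were found at 32 of the 866 ATM promoter regions, 3.70% (2.63 to 5.17), against 1.48% of windows (odds ratio 2.55, exact p = 6.44e-06). The difference was not found against the other peaks of the same antibody, a comparison added after the data were examined. HMGA2 peaks touched 3.26% of the other γ-H2AX peaks (odds ratio 0.909, exact p = 0.507) and 3.08% of the other ATM peaks (1.21, p = 0.278).

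Olfactory receptor genes, the large family of odorant receptors of the nasal epithelium, were the only list of the 16 that passed the test at 1 kb. A γ-H2AX peak lay at an end of 75 of the 1106 genes, 6.78% (5.44 to 8.42), against 24.2% of other genes (odds ratio 0.228, Fisher's exact test, adjusted p = 6.75e-49). For ATM it was 112 genes, 10.1% against 16.5% (odds ratio 0.572, adjusted exact p = 1.29e-07), and 25 genes were in the γ-H2AX promoter list, 2.26% against 9.39% (0.223, adjusted p = 3.06e-19). HMGA2 peaks lay at 213 genes, 19.3% against 17.8% (odds ratio 1.1, exact p = 0.227, adjusted p = 0.836). The γ-H2AX odds ratio was 0.208 times that of HMGA2 (95% bootstrap interval 0.154 to 0.269) and 0.399 times that of ATM (0.295 to 0.545). The bootstrap drew single genes, and the exact tests also treat genes as independent. Receptor genes in tandem arrays may not be, so these intervals may be too narrow and the p values too small. Within 500 bp of gene ends the ATM call was lost (odds ratio 0.683, adjusted exact p = 0.0514). Gene length was not matched. In a short gene the windows of both ends overlap and cover less sequence, and at Olfr1057 the same γ-H2AX peak touched both. How much of the γ-H2AX and ATM shortfall against other genes this makes up was not tested, whereas ratios between antibodies used the same windows. Single members with high scores, among them Olfr1151 (HMGA2, 51.6), Olfr507 (ATM, 51.1), Olfr585 (HMGA2, 47.6) and Olfr1057 (γ-H2AX, 41.7), are in tandem arrays of similar sequence and are uncertain.

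**Figure D4:**
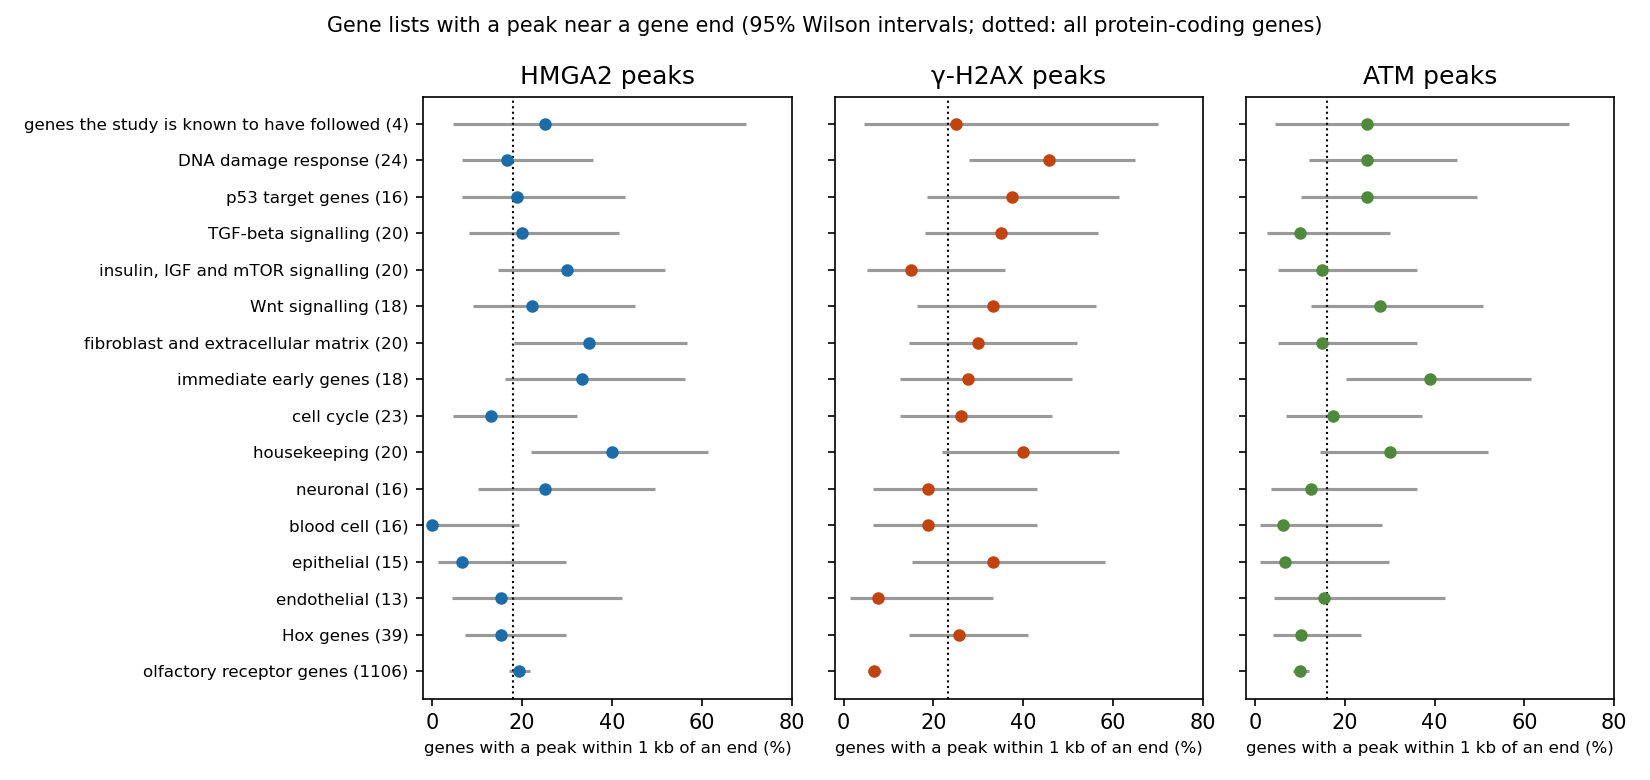
Percent of the genes of each list (size in brackets) with a peak within 1 kb of a gene end in wild-type MEF, for HMGA2, γ-H2AX and ATM, with 95% Wilson intervals and the share among all protein-coding genes as a dotted line. Olfactory receptor genes lie at 6.78% for γ-H2AX and 10.1% for ATM, below the dotted lines, and at 19.3% for HMGA2.

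Genes of the DNA damage response carried γ-H2AX peaks at 11 of 24 members, 45.8% against 23.3% of other genes, which did not pass the correction (Fisher's exact test, p = 0.0144, adjusted p = 0.199). Among them were Atm, Mdc1, the γ-H2AX-binding mediator (score 32.4), Trp53bp1, Nbn and Chek2. HMGA2 peaks lay at 4 members, the highest at Xrcc5, which encodes the Ku80 subunit (42.2), and ATM peaks at 6, the highest at Rad50 of the MRN complex (35.4) and at Lig4, the ligase of end joining (32.2). Immediate early genes had ATM peaks at 7 of 18 members (exact p = 0.0174, adjusted p = 0.199), among them Egr3 (43.9), with HMGA2 at 6, including Junb (30.3), and γ-H2AX at 5, including Myc (29.2) and Klf4 (29.1). Housekeeping genes had HMGA2 peaks at 8 of 20 members (exact p = 0.0170, adjusted p = 0.199), with γ-H2AX at 8, including the ribosomal protein gene Rpl13a (33.3), and ATM at 6, including Ywhaz (29.9). Within 5 kb of gene ends, 8 of the 80 tests passed, among them γ-H2AX at 18 of 20 genes in each of the TGF-beta, fibroblast and housekeeping lists, 90% against 58.5% of other genes (adjusted exact p = 0.0493). HMGA2 peaks were fewer there at epithelial genes, 2 of 15 or 13.3% against 52.4% (adjusted exact p = 0.0483).

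No other list passed at 1 kb. Among 16 p53 target genes, HMGA2, γ-H2AX and ATM peaks lay at 3, 6 and 4, with γ-H2AX at Sesn2 and Zmat3 (44.5) and HMGA2 at Mdm2, the ubiquitin ligase of p53 (36.5). In the same order of antibodies, peaks lay at 4, 7 and 2 of 20 TGF-beta genes, with γ-H2AX at the receptor gene Tgfbr3 (30.7). They lay at 6, 3 and 3 of 20 insulin, IGF and mTOR genes, with HMGA2 at Akt1 (27.6) and Igf2bp2 (25.6), and at 4, 6 and 5 of 18 Wnt genes, with γ-H2AX at the transcription factor gene Lef1 (36.5). Fibroblast and extracellular matrix genes had 7, 6 and 3 of 20, with HMGA2 at the growth factor receptor genes Pdgfra (29.8) and Pdgfrb (26.3) and at Col3a1, a fibrillar collagen (28.6). Cell cycle genes had 3, 6 and 4 of 23, with γ-H2AX at the mitotic kinase gene Aurkb (38.8) and at Ccnd2 (29.8). Hox genes had 6, 10 and 4 of 39, with γ-H2AX at Hoxd8 (37.3). Lists of other cell types had 4, 3 and 2 of 16 for neuronal, 0, 3 and 1 of 16 for blood cell, 1, 5 and 1 of 15 for epithelial and 2, 1 and 2 of 13 for endothelial genes.

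Of the genes the study is known to have followed, each antibody had a peak at 1 of 4. Mtor, the kinase of growth signalling, had an HMGA2 peak on chromosome 4 at 148447395 to 148447598 with a score of 31.2 and its centre at -1086 bp from the annotated start of the gene. Igf1, an insulin-like growth factor, had a γ-H2AX peak on chromosome 10 at 87857716 to 87857887 (score 20.5). ATM peaks of Igf1 lay at the same end, at 87858484 to 87858645 (22.0), which is the region in the ATM promoter list, and at the opposite end, at 87936099 to 87936277 (30.0). Gata6, a transcription factor of endoderm and heart, Hmga2 and H2ax had no peak within 1 kb of an end in any of the 3 lists. Atm itself had a γ-H2AX peak on chromosome 9 at 53536701 to 53536842 (25.3) and an ATM peak at its other end (20.9). With the peak lists alone, an absent peak does not show absent binding, since peaks under the authors' threshold are not in them.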

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

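Windows at gene ends, densities per chromosome, coverage ratios, peaks without wide sites and other peaks as background were chosen only after the results were seen, and the remaining alternatives before the data were examined. Of 119 recomputed values of the comparisons, 84 kept their direction and side of the threshold, or their size. All 21 alternatives of the pairwise overlaps did so, with ratios from 1.30 to 586. Peaks with a score of 50 or more kept 4 of 27. There the shares at gene ends, by rotation permutations, stood at 0.981 (HMGA2, p = 0.959), 1.17 (γ-H2AX, p = 0.366) and 1.07 times rotation (ATM, p = 0.735), and the odds at 1.24 (γ-H2AX to HMGA2), 1.098 (γ-H2AX to ATM) and 1.13 (ATM to HMGA2). Counts of genes and regions were too low at this filter to say whether a result held. The promoter lists, of 12 and 4 genes, had 0 in common, HMGA2 touched 0 regions of the γ-H2AX list (odds ratio 0) and 1 of the ATM list (4.80, exact p = 0.194), genes with 2 antibodies numbered 0, 0 and 0 where 0.0305, 0.0238 and 0.0189 were expected, and 0 list tests passed. Odds ratios of olfactory receptor genes, 0.671 (HMGA2), 0 (γ-H2AX), 1.11 (ATM) and 0 (γ-H2AX promoter list), rested on 1, 0, 1 and 0 genes. Spearman correlations between scores became 1 (HMGA2 and γ-H2AX, 6 peaks), 0.496 (HMGA2 and ATM, 19 peaks) and 0.574 (γ-H2AX and ATM, 17 peaks), and densities on X against autosomes 1.58 (HMGA2), 0.499 (γ-H2AX) and 0.754 (ATM).

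With the 10000 highest-scoring peaks, the ATM share at gene ends was 0.933 (rotation permutation p = 0.0719) and the X densities were 1.09 (HMGA2) and 0.540 (γ-H2AX). Against other peaks of the same antibody, HMGA2 at the promoter lists gave odds ratios of 0.909 (γ-H2AX, reversed) and 1.21 (ATM). Within 5 kb of gene ends 8 list tests passed, and the ATM promoter list at olfactory receptor genes passed at 0.483. Within 500 bp, ATM at these genes gave 0.683 (adjusted exact p = 0.0514). Median tags across positions of the mean profile gave centre-to-flank ratios of 4.19 (HMGA2), 2.40 (γ-H2AX) and 2.48 (ATM). These are not medians across peaks and do not test the weight of a few sites. Without chromosomes 7 and 11, r of γ-H2AX was 0.0406, reversed. Except where the filter left few peaks, the cause was not tested. Of 144 peaks at named genes, 66 lay outside windows of 500 bp with no other peak of that antibody inside, 70 kept the same best score and 8 gave way to another peak; within 5 kb, 126 kept it and 18 did not. A ratio for peaks of all 3 lists at scores of 50 or more could not be formed, since rotations gave 0, lists matched on CpG content and shares at start sites were not run, and no paired analysis was possible because each group had 1 library.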

Other observations

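Except for the shift of 50 to 100 kb, which was planned, the tests in this part were chosen only after the results were seen. Chromosomes rich in genes carried fewer HMGA2 peaks. Over the 19 autosomes, the density of HMGA2 peaks fell with that of protein-coding genes (r = -0.832, permutation p = 1e-05, the smallest the permutations could give, adjusted p over 3 relations 3e-05, rho = -0.714 with p = 0.00072). Without chromosomes 7 and 11, the farthest from the median gene density, r was -0.696. For ATM r was -0.658 (permutation p = 0.00201, adjusted p = 0.00301, rho = -0.542, and r = -0.480 without those chromosomes), and for γ-H2AX -0.269 (permutation p = 0.268, rho = -0.0947), which turned to 0.0406 without those chromosomes.

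Of the 3 lists, γ-H2AX had the lowest density on the X chromosome. Its density of γ-H2AX peaks was 0.670 times that of the autosomes (95% interval 0.652 to 0.688), whereas HMGA2 stood at 0.992 (0.973 to 1.01) and ATM at 0.933 (0.911 to 0.954). With the 10000 highest-scoring peaks HMGA2 turned to 1.09 (1.01 to 1.18) and γ-H2AX stood at 0.540, and with scores of 50 or more HMGA2 stood at 1.58 (1.264 to 1.962), γ-H2AX at 0.499 and ATM at 0.754. Vomeronasal receptor genes, another large family of chemosensory receptors, had γ-H2AX peaks at 11.05% of 353 members, and ATM and HMGA2 peaks at 16.1% each.

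Peaks of the 3 lists overlapped more often than after rotation. Density of peaks shared over 50 kb or more was argued against as the whole cause, since a shift of 50 to 100 kb left the lowest ratio of the pairs at 1.41 with a lower bound of 1.37. Part of the excess was local, as shifts of 0.5 kb left 1.20 for HMGA2 with γ-H2AX, 1.25 for HMGA2 with ATM and 1.37 for γ-H2AX with ATM. Broad sites were argued against too, with a lowest ratio of 1.49 (lower bound 1.44) without peaks over 500 bp wide. A background that every library of these cells shares, such as open chromatin or repeats that attract reads, may account for the overlap and cannot be told apart from shared binding, since γ-H2AX and ATM coverage around HMGA2 peaks correlated at 0.999944 across positions and no input profile was used.

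Olfactory receptor genes carried few γ-H2AX peaks, in windows not matched for gene length. A low share of γ-H2AX peaks at all gene ends of the wider region was argued against, as other genes within 500 kb had them at 24.1% (21.6 to 26.8). Peak density between the receptor genes was not measured, so a low density there stays open. Reads lost between near-identical receptors were argued against as the whole cause, because HMGA2 peaks did not fall short there by the same factor and the ratio of the odds ratios was 0.208 (0.154 to 0.269). The base composition of their ends may play a part and stays open, since vomeronasal receptor genes also fell short (odds ratio 0.384) and no genome was used to match base composition. Silence of the receptors in fibroblasts also stays open, as expression was not measured, although the 60 markers of neuronal, blood, epithelial and endothelial cells had γ-H2AX peaks at 20% (11.8 to 31.8) against 6.78%, which counts against silence alone if these are silent too.

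The X chromosome carried few γ-H2AX peaks. Its gene density was argued against as the cause, since X lay -6.53 residual SDs from the line of the autosomes, at 33.3 peaks per Mb where 50.6 were predicted, against -3.41 for ATM and -1.75 for HMGA2. A few deserts were argued against too for the part covered by 16 bins of 10 Mb, which left out the first 10 Mb. These bins held 21.9 to 43.6 peaks per Mb against an autosomal mean of 49.6. The lowest autosome, chromosome 7, held 43.2. Fewer X copies in the cells of the γ-H2AX library may explain the deficit and cannot be told apart from a lower level of the mark. The sex of the cells is not in the labels, and mapping on Y and a loss of X were not measured. The first 3 Mb of the Y chromosome gave 2 γ-H2AX peaks per Mb, 2 for HMGA2 and 3.67 (1.83 to 6.56) for ATM. The autosomal means were 49.6, 59.4 and 46.7 in the same order. Y peaks were thus rare in every list and did not set the γ-H2AX library apart from that of HMGA2. No biological explanation of the density on X was tested, and the knockout libraries were not analysed here.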
